A study of Hordeum vulgare with 24 samples.

How the data were processed

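RNA was sequenced from inflorescences of wild-type and HvMADS1-mutant barley at 2 temperatures and 2 stages, 3 libraries per group and 24 in all. Per the labels' protocols, total RNA of pooled spikes was made into libraries with a TruSeq RNA kit. Per the submitters' processing notes, HISAT2 and HTSeq were used; their versions, the genome build and the annotation are not given in the sources used here. The deposited count table holds whole read counts per gene identifier, not normalized. The deposited FPKM table holds the same counts divided by a fixed gene length and the library's total: recomputed values differed from it by a relative 9.9e-08 at most. It is therefore no independent measurement. Whether counting used strand is not given, so reads of overlapping or antisense genes, and of near-identical copies, cannot be assigned with certainty.

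Library totals ran from 13283533 to 19864259, so that 3 counts, the floor used for a gene with no read, stood at 0.151 to 0.226 CPM per library. Floors over a group sum its 3 libraries. Intervals and floors cover counting error only. No read was counted in any library for 12351 of the 39734 identifiers. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr, libraries scaled with TMM, and 8 group means fitted to all 24 libraries, so that all groups share 1 estimate of the spread. Quasi-likelihood F tests gave 14 contrasts: genotype, temperature and stage, each in 4 settings, and the genotype by temperature interaction at each stage. P values were adjusted by Benjamini-Hochberg over the 18394 genes tested, and a gene was called at an adjusted p under 0.05. Standard errors are the fold change over the square root of F. Levels are TMM-scaled CPM, as mean ± SD.

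The script was tested on simulated counts for mads1 against WT at LT W2.5 with 17652 genes tested and 200 changed genes. With the dispersions of all 24 libraries, 43.0% of 2-fold and 90.0% of 4-fold changes were recovered, and 2.92% of the calls were false. With the dispersions found without WT_HT_W2.5 replicate 3, on 17777 genes, 81.0% and 100% were recovered, and 1.63% were false. All groups were simulated from the WT LT W2.5 means, with the spread of a gene alike in every library. No simulated library stood apart as WT_HT_W2.5 replicate 3 does in the data. The false shares therefore do not cover the comparisons that hold that library.

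Gene lists were fixed before the data were examined. Of these, 17 were to be matched by gene description, and none matched because no description is paired with the identifiers in the tables used here. They cover meristem regulators, hormones, heat and cold response, the clock, cell cycle, histones, ribosomes, photosynthesis, cell wall, anther, defence, sugars, grain and epidermis, and were not analysed here. The MADS-box list holds 17 identifiers from knowledge of the family, neither paired with names in the files nor checked by sequence. It was tested with camera (limma 3.58.1, preset correlation, then estimated correlation) and fry. The rule fixed before the data were examined named HvMADS1 and, per genotype or temperature comparison, up to 4 called list members at 1 CPM or more. Where none was called it took the 2 members of highest mean CPM. Here all called members are named instead, in the stage and interaction comparisons too, which departs from that rule. Of the unnamed identifiers the rule took at most 2 that rose and 2 that fell per family of comparisons. These were taken by size of change among called genes with at least 5 CPM and groups that did not overlap. The separation of groups was not asked of the interactions.

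Alternatives were other scaling factors, no filter, DESeq2 1.42.0, robust empirical Bayes, only the libraries compared, replicate number as a block, limma on log2 FPKM with a pseudocount of 1 or 0.1, and leaving out each library. Leaving out WT_HT_W2.5 replicate 3 was thereby planned for the 4 comparisons that hold it. Chosen after the data were seen were the same fit for the other 10 comparisons, and the fits that leave it out together with mads1_HT_W3.5 replicate 3, with a block, with DESeq2 or with the compared groups only. All libraries stayed in the reported tests. Replicate pairs differed by 2.64 to 438 times sampling noise, so no library was taken as a duplicate.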

Results

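The study measured gene expression by RNA sequencing in developing inflorescences (young spikes) of the barley cultivar Golden Promise. Wild-type plants (WT) were compared with plants mutant for HvMADS1 (mads1), a gene of the SEPALLATA group of MADS-box transcription factors that act in floral organ and meristem identity. Plants were grown at 15 °C by day and 10 °C by night (LT) or at 25 °C by day and 20 °C by night (HT), and spikes were taken at Waddington stages W2.5 and W3.5. Each of the 8 groups held 3 libraries, and per the labels each library came from a pool of spikes and is a biological replicate. Library totals ran from 13283533 to 19864259 counted reads. Of 39734 gene identifiers, 18394 passed the filter on low counts and were tested.

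One library stood apart from the other 23. WT_HT_W2.5 replicate 3 had a TMM scaling factor of 0.575, against 0.959 to 1.08 in the others. Its highest rank correlation with any library was 0.921, while the lowest between any pair of the other 23 was 0.948. Its 100 most abundant genes took 26.9% of the counts. In a fit without it the common dispersion fell to 0.0173 from 0.0685. Counts of called genes are therefore given for all 24 libraries and, beside them, without this library.

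**Figure D1:**
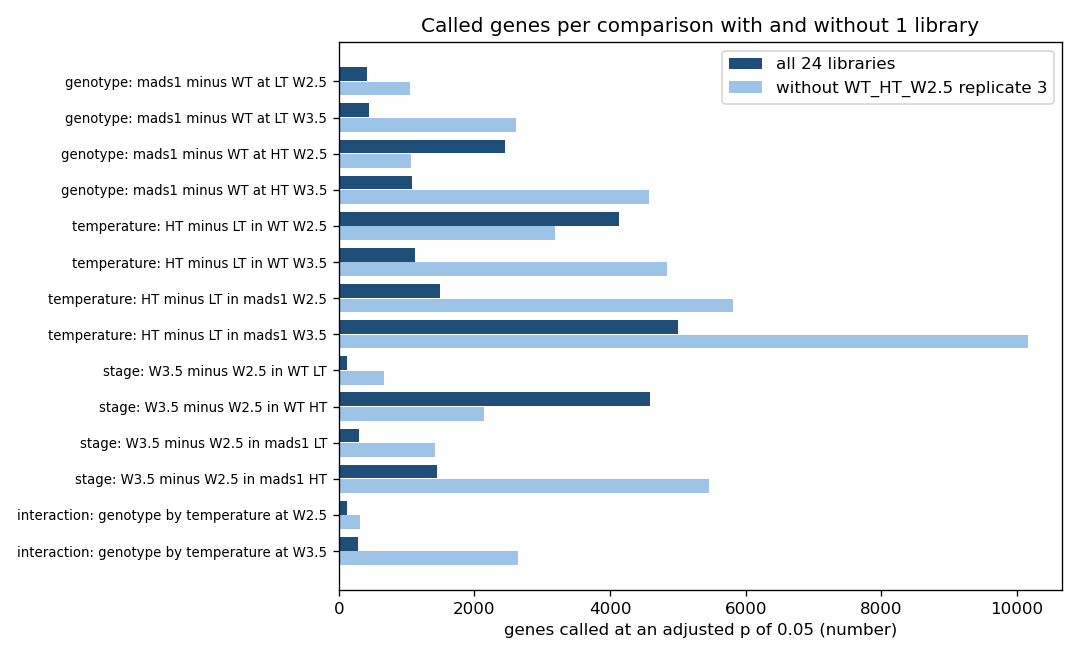
Number of genes called at an adjusted p of 0.05 (horizontal axis) in each of the 14 comparisons (vertical axis), with all 24 libraries (dark bars) and without WT_HT_W2.5 replicate 3 (light bars). The count in WT at HT between stages went from 4588 to 2141, and that of mads1 between temperatures at W3.5 from 5003 to 10157.

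The gene names used below come from a list of 17 MADS-box identifiers fixed before the data were examined, from knowledge of the barley family. Neither the files nor the reference table pair the identifiers with names, and the names were not checked by sequence. Of the 17, 13 were tested; those named HvMADS2, HvMADS4, HvMADS13 and HvMADS21 had at most 4 counts in any library.

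The mutated gene came first, as a check on the labels. HvMADS1 (HORVU4Hr1G067680) stood at 40.7 ± 3.86 CPM (SD, n = 3) in WT and 17.5 ± 4.95 in mads1 at LT W2.5, and at 59.1 ± 3.45 and 46.0 ± 4.02 at LT W3.5. At HT W2.5 the levels were 8.65 ± 1.95 in WT and 10.4 ± 2.68 in mads1. At HT W3.5 it stood at 61.8 ± 2.84 in WT, whereas the 3 mads1 libraries read 0, 0.331 and 13.3 CPM. Only this last difference passed the test, with a log2 fold change of -3.79 (SE 0.84, edgeR adjusted p = 0.0099, lower in 3 of 3 libraries). Its size rests on replicate 3 of mads1_HT_W3.5: without that library it was -8.39, and without mads1_HT_W3.5 replicate 1 it was -3.20. The difference at LT W2.5 was not called, although the libraries did not overlap, at 36.9 to 44.6 CPM in WT and 14 to 23.2 in mads1. The spread is shared by all 8 groups, so the unlike mads1_HT_W3.5 libraries also enter the tests of this gene in the other groups. The kind of mutation is not given in the sources used here, so a transcript that remains does not speak against the labels. The mads1 groups differed among themselves in this transcript, and whether they came from the same allele or seed lot is not given either.

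**Figure D2:**
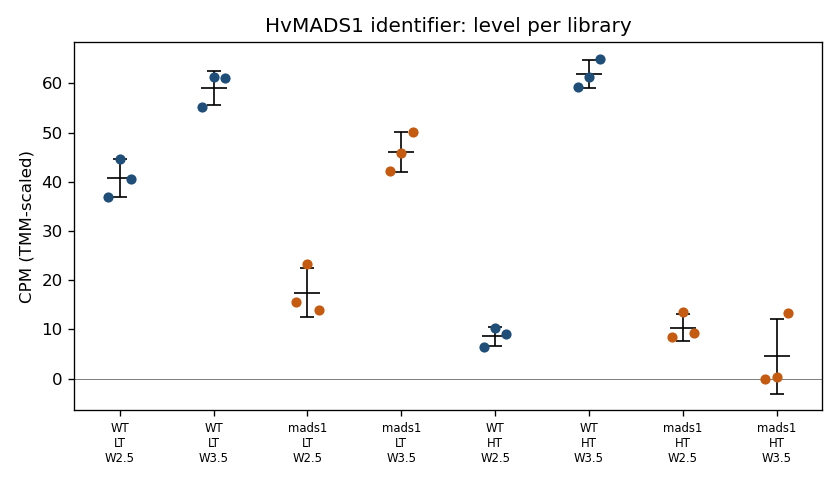
Level of the HvMADS1 identifier in CPM (vertical axis) for the 8 groups (horizontal axis); points are libraries, blue for WT and orange for mads1, and bars are the mean with its SD (n = 3). WT at HT W3.5 averaged 61.8 CPM, and the mads1 libraries of that group read 0, 0.331 and 13.3.

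At LT, the question was what the mutation changed under the cooler regime. At W2.5 the floral regulators HvMADS6 (HORVU6Hr1G066140, of the AGL6 group) and HvMADS7 (HORVU7Hr1G054220) and HvMADS8 (HORVU5Hr1G076400), both of the SEPALLATA group, were lower in mads1. HvMADS6 stood at 0.546 ± 0.282 CPM in mads1 against 9.91 ± 4.59 in WT (log2 fold change -4.15, SE 0.51, edgeR adjusted p = 3.4e-05). HvMADS8 stood at 0.0961 ± 0.118 against 1.82 ± 1.65 (log2 fold change -4.07, SE 0.84, adjusted p = 0.0075). HvMADS7 had no read in the 3 mads1 libraries and 1.33 ± 1.52 CPM in WT, at least 22.4-fold lower against a floor of 3 counts over the group, and at least 7.81-fold without WT_LT_W2.5 replicate 2. The call of HvMADS7 was lost without any 1 of the 3 mads1_LT_W2.5 libraries (adjusted p 0.056 to 0.062). That of HvMADS8 was lost without WT_LT_W2.5 replicate 2 or mads1_LT_W2.5 replicate 1 or 3 (0.053 to 0.056), and its change was -3.11 without WT_LT_W2.5 replicate 2 and -5.56 without mads1_LT_W2.5 replicate 2. In all 3 genes WT_LT_W2.5 replicate 2 read highest and replicate 3 lowest of the WT libraries, at 14.7 and 5.55 CPM for HvMADS6. At LT W3.5 the mads1 and WT means were 30.9 and 33 CPM for HvMADS6. They were 21 and 18.4 for HvMADS7, and 15.8 and 13.2 for HvMADS8. Whether the mads1 spikes were sampled earlier in development is taken up in the last paragraph and was not decided. No other of the 13 members was called, and 7 were called when adjusted over the list alone. Without WT_HT_W2.5 replicate 3, 5 were called lower: HvMADS14 (HORVU5Hr1G095630, the vernalization gene VRN1; -0.35, adjusted p = 0.016) and HvMADS3 (HORVU3Hr1G026650, of the AGAMOUS group; -3.15, 0.044) joined these 3. The list was lower by camera (adjusted p = 8.7e-09), a call lost with an estimated correlation (adjusted p = 0.053). By fry it was also called lower (adjusted p = 0.01).

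At LT W3.5 none of the 13 MADS members was called by edgeR, with 1 at an unadjusted p under 0.05 and 1 called by DESeq2, which gave no adjusted p for HvMADS1 in any comparison. HvMADS15 (HORVU2Hr1G063800, of the APETALA1 group) was called higher in mads1 without WT_HT_W2.5 replicate 3 (0.29, adjusted p = 0.03). Other identifiers differed strongly. HORVU2Hr1G031640 stood at 331 ± 47.7 CPM in mads1 and had no read in WT, at least 6438-fold higher, and HORVU3Hr1G065060 stood at 55.1 ± 2.38 CPM against no read, at least 1072-fold higher. HORVU5Hr1G054000 was lower in mads1, at 0.164 ± 0.1 against 25.4 ± 0.895 CPM (log2 fold change -7.25, SE 0.54, edgeR adjusted p = 3.5e-08). Over all genes, 418 were called at W2.5 (259 higher and 159 lower in mads1) and 445 at W3.5 (313 and 132). The counts without WT_HT_W2.5 replicate 3 were 1047 (530 and 517) and 2615 (1520 and 1095); without WT_LT_W3.5 replicate 3, 291 were called at W3.5.

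At HT, the comparison asked what the mutation changed in the warm regime. At W3.5 HvMADS1 was the 1 member called, and lower in mads1. The levels of 4 other floral regulators there were 14.0 ± 0.525 CPM in mads1 against 23.3 ± 2.09 in WT for HvMADS6, 7.32 ± 2.94 against 17.5 ± 1.94 for HvMADS7, 8.94 ± 1.11 against 12.9 ± 1.28 for HvMADS8 and 13.3 ± 4.45 against 25.4 ± 3.18 for HvMADS16 (HORVU7Hr1G091210, a petal and stamen identity gene). These 4 did not pass the test with all libraries. Without WT_HT_W2.5 replicate 3, 5 members were called lower and 1 higher. The lower ones were HvMADS1, HvMADS6 (adjusted p = 0.039), HvMADS7 (0.034), HvMADS16 (0.014) and HvMADS58 (HORVU1Hr1G029220, of the AGAMOUS group; 0.02), and the higher one was HvMADS14 (0.0027). HvMADS8 was not called in that fit either (0.3). The list was lower by camera (adjusted p = 0.0013), a call lost with an estimated correlation (adjusted p = 0.25). By fry it was not called (adjusted p = 0.065).

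At HT W2.5 HvMADS18 (HORVU0Hr1G003020, of the APETALA1 group) was the 1 called member, at 57.3 ± 1.91 CPM in mads1 against 96.2 ± 55.7 in WT (log2 fold change -0.74, SE 0.23, edgeR adjusted p = 0.043). Without WT_HT_W2.5 replicate 3 the change was -0.15 and the call was lost (adjusted p = 0.44), as it was without any 1 mads1_HT_W2.5 library (lowest 0.11). In the fit without WT_HT_W2.5 replicate 3 HvMADS32 (HORVU3Hr1G068900) was called higher in mads1 (0.47, adjusted p = 0.024). The median of the list was 0.28 and fry gave a higher direction while camera gave a lower one, none of them past its threshold (camera adjusted p = 0.89). HORVU6Hr1G018030 stood at 0.138 ± 0.0839 CPM in mads1 against 73.9 ± 25.9 in WT (log2 fold change -8.97, SE 0.48, adjusted p = 5.4e-10). This difference was not particular to the warm regime. The mads1 and WT means of HORVU6Hr1G018030 were 0.157 and 43 CPM at LT W2.5, and 0.186 and 43.9 at LT W3.5. At HT W3.5 they were 5.87 and 131 CPM. Over all genes, 2446 were called at W2.5 (459 higher and 1987 lower in mads1), and 1062 (480 and 582) without that library, against 5750 without WT_HT_W2.5 replicate 1, 5466 without its replicate 2, and 579, 601 and 665 without mads1_HT_W2.5 replicates 1, 2 and 3. Of the 2446 genes, 763 were also called without WT_HT_W2.5 replicate 3. At W3.5, 1072 were called (719 and 353), 4572 (2579 and 1993) without it, 478 without mads1_HT_W3.5 replicate 3, and 442, 621 and 554 without WT_HT_W3.5 replicates 1, 2 and 3.

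In WT, 9 of the 13 MADS members were called lower in the warm regime at W2.5 and none higher. HvMADS1 fell by 2.24 on the log2 scale (SE 0.79, edgeR adjusted p = 0.048, lower in 3 of 3 libraries). This call was lost in 5 of the 6 fits that each left out 1 library (adjusted p 0.052 to 0.096), and held only without WT_HT_W2.5 replicate 3 (0.024). The libraries did not overlap, at 36.9 to 44.6 CPM at LT and 6.49 to 10.3 at HT. Here too the shared spread holds the unlike mads1_HT_W3.5 libraries. HvMADS5 (HORVU7Hr1G025700, of the SEPALLATA group) fell from 19.5 ± 4.47 to 3.89 ± 1.12 CPM, a log2 fold change of -2.34 (SE 0.26, adjusted p = 1.7e-05). HvMADS6 fell from 9.91 ± 4.59 to 0.254 ± 0.278 CPM, a log2 fold change of -5.51 (SE 0.62, adjusted p = 2.0e-05; -6.54 without WT_HT_W2.5 replicate 3). HvMADS32 fell from 107 ± 14.7 to 57.0 ± 20.1 CPM. Among the 9, HvMADS15 and HvMADS16 lost their calls without WT_LT_W2.5 replicate 2 (0.077 and 0.054). HvMADS3 lost its call without that library (0.27) or without WT_HT_W2.5 replicate 1 or 2 (0.073 and 0.07). The number was also 9 when adjusted over the list alone, and 11 members were lower without WT_HT_W2.5 replicate 3, HvMADS34 (HORVU5Hr1G095710, of the SEPALLATA group; -1.16) and HvMADS18 (-0.87) in addition. The list was lower by camera (adjusted p = 6.6e-06), which did not hold with an estimated correlation (adjusted p = 0.12, and 0.038 without that library). By fry it was called lower (adjusted p = 6.0e-04).

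At W3.5 no MADS member was called between HT and LT in WT by edgeR, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2. With WT_HT_W2.5 replicate 3 left out, 2 were called lower: HvMADS34 (-0.71, adjusted p = 9.3e-05, 100 ± 4.82 CPM at LT and 61.5 ± 7.25 at HT) and HvMADS18 (-0.47, 1.2e-04). HvMADS1 read 61.8 ± 2.84 CPM at HT and 59.1 ± 3.45 at LT, a log2 fold change of 0.07 (SE 0.73, edgeR adjusted p = 0.99). Over all genes, 4127 were called at W2.5 (3098 higher and 1029 lower at HT) and 1130 at W3.5 (700 and 430). Leaving out WT_HT_W2.5 replicate 3 gave 3191 (1748 and 1443) and 4836 (2556 and 2280). Of the 4127 genes called at W2.5, 1931 were also called in that fit. The count at W2.5 was 1493, 2462 and 1773 without WT_LT_W2.5 replicates 1, 2 and 3, and 6842 and 6560 without WT_HT_W2.5 replicates 1 and 2. At W3.5 it was 620, 551 and 564 without WT_LT_W3.5 replicates 1, 2 and 3, and 581 and 559 without WT_HT_W3.5 replicates 2 and 3. An edgeR fit of the compared libraries alone called 0 genes at W2.5 (1406 at an unadjusted p under 0.05, and 407 by DESeq2) and 7402 at W3.5.

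In mads1, 4 of 13 members were called lower in the warm regime at W2.5 and none higher with all libraries. Without WT_HT_W2.5 replicate 3, 5 were called lower, HvMADS32 (-0.43) in addition, and 2 higher, HvMADS14 (0.27, adjusted p = 0.022) and HvMADS58 (1.29, 0.031). HvMADS5 fell by 1.93 on the log2 scale (SE 0.26, edgeR adjusted p = 1.0e-04), and HvMADS34 fell from 104 ± 12.9 to 43.4 ± 4.31 CPM. HvMADS15 and HvMADS18 were the others. The calls of HvMADS34 and HvMADS18 at W2.5 were lost in 5 and 6 of 7 fits that each left out 1 library (up to 0.11 and 0.12). Both held without WT_HT_W2.5 replicate 3 (2.0e-07 and 5.0e-07), and HvMADS34 also without mads1_LT_W2.5 replicate 1. At W3.5, 5 fell and 1 rose (10 and 1 without WT_HT_W2.5 replicate 3, with HvMADS3, HvMADS7, HvMADS16, HvMADS18 and HvMADS32 lower in addition). HvMADS1 fell by 3.36 (SE 0.83, adjusted p = 0.0049; a change of -7.96 without mads1_HT_W3.5 replicate 3 and of -2.77 without its replicate 1), HvMADS58 fell from 8.25 ± 2.04 to 3.01 ± 0.813 CPM, and HvMADS14 rose from 335 ± 48.0 to 442 ± 26 CPM. Without mads1_HT_W3.5 replicate 3 the calls of HvMADS5 (-0.62, adjusted p = 0.076), HvMADS34 (-0.91, 0.12), HvMADS14 (0.36, 0.11), HvMADS58 (-1.29, 0.094) and HvMADS6 (-1.11, 0.1) were lost, while that of HvMADS1 held in all 7 fits (highest 0.018). HvMADS34 and HvMADS6 also lost theirs without any 1 of the other libraries compared, HvMADS5 without mads1_LT_W3.5 replicate 3, HvMADS14 without mads1_LT_W3.5 replicate 1 or mads1_HT_W3.5 replicate 2, and HvMADS58 without mads1_LT_W3.5 replicate 2 or 3 or mads1_HT_W3.5 replicate 2 (0.051 to 0.18 over these). Adjusted over the list alone, 4 and 8 were called. Camera called the list lower at both stages (adjusted p = 0.042 and 2.9e-04), and neither call held with an estimated correlation (adjusted p = 0.46 and 0.21). Fry called it lower at W3.5 (adjusted p = 0.0014) and did not call it at W2.5 (0.11).

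Some identifiers in mads1 were present in one temperature and absent or nearly so in the other at the same stage. HORVU6Hr1G050370 stood at 46.9 ± 1.39 CPM at HT W2.5 with no read at LT W2.5, at least 794-fold higher. At HT W3.5 it read 0.0655, 0 and 11.7 CPM in replicates 1, 2 and 3, so its presence was not shared by all HT libraries. HORVU2Hr1G001180 had no read at HT W2.5 and 11.8 ± 1.26 CPM at LT W2.5, at least 195-fold lower. At W3.5 this identifier averaged 0.0964 CPM at HT and 15.4 at LT. At W3.5 HORVU1Hr1G039430 had 1 read at HT against 26 ± 1.22 CPM at LT, a ratio of 1246 (95% counting interval 224 to 49205). The 1 read lay in replicate 3, without which this identifier was at least 289-fold lower. At HT W2.5 it averaged 3.79 ± 0.721 CPM, so it was not absent from all HT libraries. Neither HORVU1Hr1G039430 nor HORVU2Hr1G001180 had a read in WT, and HORVU6Hr1G050370 had at most 1 per WT group. HORVU3Hr1G065630 averaged 26.1 ± 44.0 CPM at HT W3.5 through replicate 3, and its call was lost without that library (adjusted p = 0.11). Over all genes, 1491 were called at W2.5 (789 higher and 702 lower at HT) and 5003 at W3.5 (2584 and 2419); without WT_HT_W2.5 replicate 3 there were 5808 and 10157. The count at W2.5 was 791 and 735 without mads1_LT_W2.5 replicates 2 and 3, and 858, 868 and 900 without mads1_HT_W2.5 replicates 1, 2 and 3.

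Between W2.5 and W3.5 many MADS members were called higher in each genotype and temperature. In WT at LT 6 of 13 were called higher, in WT at HT 10, in mads1 at LT 9 and in mads1 at HT 10, and none was called lower. The numbers were 10, 12, 11 and 12 without WT_HT_W2.5 replicate 3. HvMADS1 in mads1 at HT was not called (-1.22, adjusted p = 0.46), and HvMADS34 in WT at HT read -0.30 with all libraries and 0.69 without that one, where it was called. In WT at LT the calls of HvMADS7, HvMADS8, HvMADS3 and HvMADS58 were lost without WT_LT_W2.5 replicate 1 (adjusted p = 0.072, 0.11, 0.19 and 0.14). The last 3 of these were lost without WT_LT_W2.5 replicate 3 too (0.098, 0.093 and 0.19), and HvMADS3 and HvMADS58 without any 1 WT_LT_W3.5 library (0.063 to 0.1). HvMADS16 rose in all 4, from 2.45 ± 1.83 to 24 ± 1.12 CPM in WT at LT (log2 fold change 3.32, SE 0.38, edgeR adjusted p = 9.4e-05; 4.09 without WT_LT_W2.5 replicate 2) and from 1.11 ± 0.223 to 13.3 ± 4.45 CPM in mads1 at HT (3.57, SE 0.40, adjusted p = 1.5e-05). HvMADS7 had no read in mads1 at LT W2.5 and 21.0 ± 5.41 CPM at LT W3.5, at least 355-fold higher. HvMADS3 rose from 0.134 ± 0.184 to 9.01 ± 0.419 CPM in WT at HT (log2 fold change 6.34; 7.85 without WT_HT_W2.5 replicate 3 and 5.75 without its replicate 2). HvMADS1 rose in WT at HT (log2 fold change 2.84, SE 0.80, adjusted p = 0.018; 0.06 without WT_HT_W3.5 replicate 3), and read 10.4 ± 2.68 and 4.55 ± 7.60 CPM at the same stages in mads1.

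**Figure D3:**
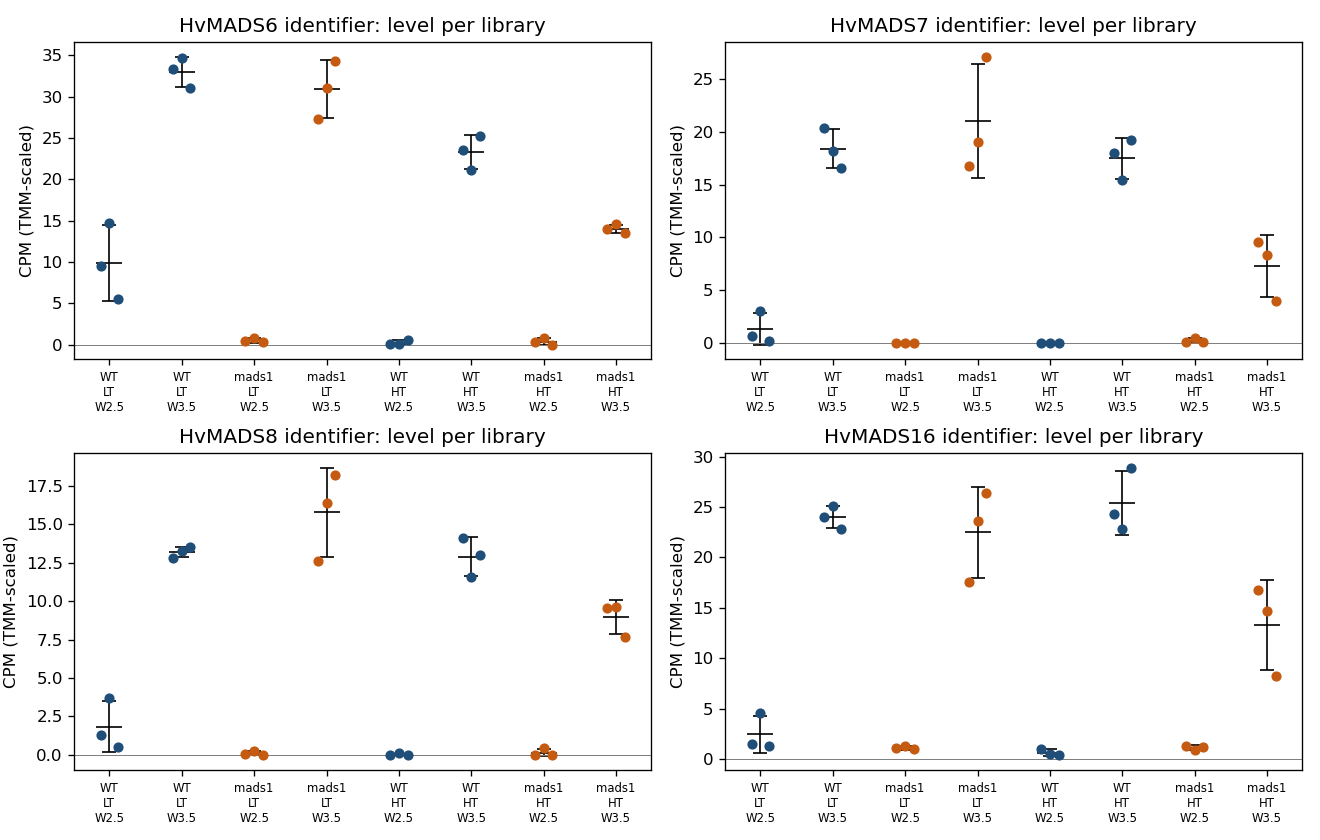
Levels in CPM (vertical axes) of the identifiers named HvMADS6, HvMADS7, HvMADS8 and HvMADS16 in the 8 groups (horizontal axes); points are libraries, blue for WT and orange for mads1, and bars are the mean with its SD (n = 3). All 4 had a higher mean at W3.5 than at W2.5 in each genotype and temperature. The rise of HvMADS6 in WT at LT was not called with all libraries. HvMADS16 in mads1 at HT went from 1.11 to 13.3 CPM.

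Camera called the list higher in the 4 stage comparisons, and these calls held with an estimated correlation (adjusted p = 0.0013, 0.017, 3.1e-04 and 0.013). Fry called it higher in all 4 (adjusted p = 1.9e-05, 5.8e-07, 4.0e-07 and 1.3e-06). Adjusted over the list alone, 9, 10, 11 and 11 members were called, in the same order. HORVU7Hr1G062070 had no read in mads1 at HT W2.5 and 11.2 ± 3.21 CPM at HT W3.5, at least 185-fold higher. It had no read in mads1 at LT or in WT at either stage, so it was present in the mads1_HT_W3.5 group only. Another 2 fell to 1 read at W3.5, HORVU3Hr1G108680 in mads1 at HT from 5.38 ± 7.63 CPM (ratio 259, 95% counting interval 46.4 to 10216, adjusted p = 0.006) and HORVU2Hr1G094780 in WT at HT from 5.04 ± 5.40 CPM (ratio 253, interval 45.4 to 9988, adjusted p = 0.0052). The ratios were 46.6 without mads1_HT_W2.5 replicate 1 and 101 without WT_HT_W2.5 replicate 3. The 1 read lay in replicate 3 of each W3.5 group, without which they were at least 60.1-fold and 54.6-fold lower. Over all genes, 117 were called in WT at LT (79 higher and 38 lower at W3.5), 4588 in WT at HT (1029 and 3559), 302 in mads1 at LT (212 and 90) and 1441 in mads1 at HT (860 and 581). With WT_HT_W2.5 replicate 3 left out they were 660, 2141 (938 and 1203), 1419 (785 and 634) and 5462. Of the 4588 genes called in WT at HT, 1474 were also called in that fit. In WT at LT the count was 55 and 36 without WT_LT_W2.5 replicates 1 and 3, and 64, 59 and 57 without WT_LT_W3.5 replicates 1, 2 and 3. In WT at HT it was 7258 and 6952 without WT_HT_W2.5 replicates 1 and 2, and 1623, 1957 and 850 without WT_HT_W3.5 replicates 1, 2 and 3. In mads1 at LT it was 180, 174 and 165 without mads1_LT_W2.5 replicates 1, 2 and 3, and 189 and 177 without mads1_LT_W3.5 replicates 2 and 3. In mads1 at HT it was 956 and 818 without mads1_HT_W2.5 replicates 2 and 3. An edgeR fit of the compared libraries alone called 0 genes in WT at HT (1661 at an unadjusted p under 0.05, and 475 by DESeq2).

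The interaction asked whether the temperature effect differed between genotypes. HvMADS6 was the 1 MADS member called at W2.5 with all libraries, at a difference of 4.99 (SE 0.97, edgeR adjusted p = 0.015). The difference was 3.73 (0.31) without mads1_HT_W2.5 replicate 2 and 6.04 without WT_HT_W2.5 replicate 3. HvMADS6 was at 9.91 ± 4.59 CPM in WT at LT and under 1 CPM on average in the other W2.5 groups. HvMADS32 was called as well without WT_HT_W2.5 replicate 3 (0.80, adjusted p = 0.01). At W3.5 none of the 13 was called by edgeR, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2. HvMADS1 had a difference of -3.43 there (SE 1.09, adjusted p = 0.14; 0.007 without WT_HT_W2.5 replicate 3), and in that fit HvMADS58 was called too (-1.83, 0.0059). Adjusted over the list alone, 5 members were called at W2.5. Camera called the list higher at W2.5 (adjusted p = 0.0022) and lower at W3.5 (8.6e-06), and neither held with an estimated correlation (adjusted p = 0.25 and 0.12). Fry called it lower at W3.5 (adjusted p = 0.029) and did not call it at W2.5 (0.099).

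HORVU3Hr1G065060 differed by -11.34 at W3.5 (SE 2.61, edgeR adjusted p = 0.042), at 55.1 ± 2.38 CPM in mads1 at LT and 0.115 ± 0.143 at HT, and 0 and 2 reads over the WT groups at LT and HT. The size of this fitted difference rests on these few reads, and it was -8.71 without WT_HT_W3.5 replicate 1 (adjusted p = 1) and -13.02 without mads1_HT_W3.5 replicate 2. HORVU2Hr1G112080 passed the test at W2.5 (adjusted p = 0.037), with no read in mads1 at HT against 5.59 ± 0.851 CPM at LT, at least 92.6-fold lower, and 1 and 2 reads over the WT groups at LT and HT. HORVU6Hr1G066050 and HORVU6Hr1G028790 differed by 7.55 and 6.22 at W3.5, and both calls were lost without mads1_HT_W3.5 replicate 3 (5.65 and 4.40, adjusted p = 0.1 and 0.17), as was that of HORVU3Hr1G065060 (-11.11, 0.074). Of 13 fits that each left out 1 library, these 3 calls were lost in 11, 11 and 9, and the call of HORVU2Hr1G112080 in 9 of 12 (highest 0.076). HORVU6Hr1G066050 and HORVU6Hr1G028790 kept theirs only without mads1_HT_W3.5 replicate 1 or WT_HT_W2.5 replicate 3. HORVU3Hr1G065060 kept its call also without WT_HT_W3.5 replicate 3 and mads1_HT_W3.5 replicate 2, each left out alone, and HORVU2Hr1G112080 kept its call only without WT_LT_W2.5 replicate 3 or WT_HT_W2.5 replicate 1 or 3. Over all genes, 126 were called at W2.5 (53 higher and 73 lower) and 277 at W3.5 (130 and 147). They were 316 and 2636 without WT_HT_W2.5 replicate 3. At W2.5 the count was 1206 and 783 without WT_HT_W2.5 replicates 1 and 2, 82 without WT_LT_W2.5 replicate 1 and 80 without mads1_HT_W2.5 replicate 1. At W3.5 it ranged from 123 (without WT_HT_W3.5 replicate 1) to 392 (without mads1_HT_W3.5 replicate 1) over the compared libraries.

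Effects were compared across genes, which are not independent replicates. The genotype effects at LT and HT correlated at r = 0.50 (rho 0.26) at W2.5 and 0.49 (rho 0.22) at W3.5. The temperature effects in WT and mads1 correlated at r = 0.38 (rho 0.44) at W2.5 and 0.51 (rho 0.67) at W3.5. At W3.5, 607 genes were called higher at HT in both genotypes against 98.3 from independent lists, and 375 lower against 56.5. These were 2187 against 738 and 1945 against 579 without WT_HT_W2.5 replicate 3, and the correlation of the temperature effects at W2.5 was r = 0.45 (rho 0.60). These pairs shared no libraries.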

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

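The tests of this part were chosen after the results were seen, except the interaction tests and the test of neighbouring genes at a window of 20. The results named first are those for which the temperature effect differed between genotypes by the interaction test itself. HvMADS6 differed by 4.99 at W2.5. Its means at LT and HT were 9.91 and 0.254 CPM in WT, and 0.546 and 0.368 in mads1, so only WT had a level to fall from. The call of HvMADS6 was lost without mads1_HT_W2.5 replicate 2 (difference 3.73, edgeR adjusted p = 0.31). HORVU2Hr1G112080 differed by -10.74 at W2.5, a fitted value whose size rests on groups with 0 to 2 reads. At W3.5 HORVU3Hr1G065060 differed by -11.34, HORVU6Hr1G066050 by 7.55 and HORVU6Hr1G028790 by 6.22. All 4 identifiers other than HvMADS6 had adjusted p values between 0.037 and 0.049.

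WT_HT_W2.5 replicate 3 differed from replicates 1 and 2 by a SD of 1.85 on the log2 scale over genes, while those replicates differed by 0.37. Of 18417 genes, 3478 were over 4-fold lower in it and 1557 over 4-fold higher. The tables argue against 3 technical explanations as the whole cause: 4 libraries with a lower total had best rank correlations of 0.966 or more, a curve of gene length took up 3.44% of the variance of its deviation, and its best correlation with any other library, 0.921, lay under the lowest between the other 23 (0.948), which an exchange within the study would not give. The genes over 4-fold higher in it had a median length of 1085 against 1575 for those over 4-fold lower, so a part by length remains. A different tissue make-up of the pool, damaged RNA or a sample from outside the study stay open. No biological explanation was tested, since the design gives none for a single library.

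Genes off (under 0.5 CPM) in one mads1 group and on (at least 5 CPM) in another numbered 13 between LT and HT at W2.5 and 14 at W3.5, against 1 and 0 in WT. Loss of HvMADS1 acting alike in every group is argued against: 8 of the 31 genes off in WT and on in mads1 at LT W2.5 were off in all libraries of another mads1 group, though 18 of the 31 stood over 4-fold above WT in every one. A warm response of mads1 alike at both stages may account for the rest, since 100% of the 13 genes kept their direction at W3.5, 9 of them by over 4-fold (12 and 7 without mads1_HT_W3.5 replicate 3); 3 met the strict limits at both stages. Plants from another seed lot at HT would give the same and cannot be told apart from it, because the labels give no lots. The mads1 HT groups also differed from each other: of the 31 genes, 17 were on at HT W2.5 and 8 at HT W3.5, against 28 at LT W3.5. A single lot at HT, or a warm response alike at both stages, would not by itself give this. The difference enters every contrast that uses mads1_HT_W3.5. Segments of another genotype stay open too: neighbouring pairs exceeded chance at the window of 20 genes (permutation p = 0.047), and not at windows of 5, 10 and 50 (p = 0.31, 0.16 and 0.47).

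HvMADS1 read 0 and 0.331 CPM in mads1_HT_W3.5 replicates 1 and 2 and 13.3 in replicate 3. A mixture with wild-type plants only is argued against, because 7 of 8 genes that were off in replicates 1 and 2 and in all WT libraries other than WT_HT_W2.5 replicate 3, and on in mads1 at HT W2.5, reached 1 CPM in replicate 3. Whether replicate 3 holds spikes like those of the mads1 HT W2.5 group stays open. Over the 9 genes off in replicates 1 and 2 and on in that group, HvMADS1 included, replicate 3 stood at a median of 35.9% of its level, but the range of 0.713 to 127% is wide for a single share of mixed plants. Such spikes would not account for all of replicate 3: 18 genes reached 5 CPM in it and stayed under 1 CPM in the other 23 libraries, and on the first principal component without WT_HT_W2.5 replicate 3 it lay at 101.9, beyond replicates 1 and 2 (55.1 and 74.8) and not between them and the HT W2.5 group (23.8 to 43.3). On the second component it lay at -26.8, within the range of the HT W2.5 group (-27.8 to -21.8), with replicates 1 and 2 at 7.6 and -2.7.

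Other ways of splitting the same libraries were counted in fits of the compared groups. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other called 574 and 0, 2181 and 0, 64 and 0, and 1981 and 0 genes for genotype (LT W2.5, LT W3.5, HT W2.5, HT W3.5). For temperature these were 0 and 0, 7402 and 0, 6145 and 0, and 7268 and 0 (WT W2.5, WT W3.5, mads1 W2.5, mads1 W3.5). For stage they were 543 and 0, 0 and 0, 746 and 491, and 3512 and 1 (WT LT, WT HT, mads1 LT, mads1 HT); the number of splits with as many genes was 10 of 10 where the real split called 0, and 1 of 10 otherwise. For the interactions 100 splits were counted, the real one among them. At W2.5 only the real split reached its 19 genes (highest other 3). At W3.5, 2 splits reached 2100 genes, the real one included (highest other 5118). With temperature labels exchanged only within a genotype, 2 of 80 splits reached 19 genes and 5 of 80 reached 2100 (highest other 5493). The real split is included in these counts too. Neither count decides on chance for an interaction, because these splits do not hold the effects of genotype and temperature: the split with 5118 genes kept the mads1 LT libraries together and mixed those of WT, which by itself gives a difference between genotypes.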

How the results depend on the processing

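The fits without WT_HT_W2.5 replicate 3 were chosen after the data were seen, except alone in the 4 comparisons that hold it; these and the other alternatives were fixed before the data were examined. Among the named genes 85 values had 1759 alternatives, of which 1553 kept their direction and side of the threshold, 177 lost the call, 29 gained it and 0 changed direction. Apart from those of HvMADS1, these values were taken because they were called with all libraries, so a change of direction was unlikely from the start. HvMADS34 between stages in WT at HT, not called and so not among them, did change direction without WT_HT_W2.5 replicate 3. DESeq2 gave no adjusted p for 15 further named values, and for 15 without that library. Counts of called genes depended on the libraries and the tool as below, and where no construction is named the cause was not tested. The common dispersion of 0.0685 with all libraries against 0.0173 without that library limits what the shared estimate of the spread can call. The estimate of 3.02 prior degrees of freedom against 4.82 goes with it.

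Whether replicate numbers pair the samples was not decided: 16 of 84 same-number pairs had a correlation of deviations over 0.1, in a range of -0.44 to 0.43. Pairs of unlike number were not computed beside them. With the replicate block the count was 1280 (genotype HT W2.5) and the other counts moved by less than 1.5 times; 6 named calls were lost. With the block and without WT_HT_W2.5 replicate 3 the counts were 1015 (genotype LT W2.5), 2677 (genotype LT W3.5), 987 (genotype HT W2.5), 4494 (genotype HT W3.5), 4808 (temperature WT W3.5), 5810 (temperature mads1 W2.5), 10135 (temperature mads1 W3.5), 650 (stage WT LT), 2112 (stage WT HT), 1387 (stage mads1 LT), 5359 (stage mads1 HT), 288 (interaction W2.5) and 2603 (interaction W3.5).

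With only the groups compared, whose spread is then estimated from fewer libraries, the counts were 2181 (genotype LT W3.5), 64 (genotype HT W2.5), 1981 (genotype HT W3.5), 0 (temperature WT W2.5), 7402 (temperature WT W3.5), 6145 (temperature mads1 W2.5), 543 (stage WT LT), 0 (stage WT HT), 746 (stage mads1 LT), 3512 (stage mads1 HT), 19 (interaction W2.5) and 2100 (interaction W3.5). Where 0 genes were called, edgeR gave 1406 genes (temperature WT W2.5) and 1661 (stage WT HT) at an unadjusted p under 0.05, and DESeq2 on the same libraries called 407 and 475. With only the groups compared and without WT_HT_W2.5 replicate 3 they were 2181 (genotype LT W3.5), 1981 (genotype HT W3.5), 1619 (temperature WT W2.5), 7402 (temperature WT W3.5), 6145 (temperature mads1 W2.5), 543 (stage WT LT), 746 (stage mads1 LT), 3512 (stage mads1 HT), 230 (interaction W2.5) and 2100 (interaction W3.5).

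DESeq2 called 774 (genotype LT W3.5), 1691 (genotype HT W3.5), 1813 (temperature WT W3.5), 2253 (temperature mads1 W2.5), 292 (stage WT LT), 516 (stage mads1 LT), 353 (interaction W2.5) and 809 (interaction W3.5). DESeq2 without WT_HT_W2.5 replicate 3 called 1187 (genotype LT W2.5), 2953 (genotype LT W3.5), 1169 (genotype HT W2.5), 4585 (genotype HT W3.5), 4938 (temperature WT W3.5), 5806 (temperature mads1 W2.5), 9950 (temperature mads1 W3.5), 930 (stage WT LT), 2442 (stage WT HT), 1597 (stage mads1 LT), 5380 (stage mads1 HT), 466 (interaction W2.5) and 3036 (interaction W3.5).

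On log2(FPKM + 1) limma called 733 (genotype HT W2.5), 2402 (temperature WT W2.5), 186 (stage WT LT) and 2429 (stage WT HT). On log2(FPKM + 0.1) it called 719 (genotype HT W2.5), 2130 (temperature WT W2.5) and 1913 (stage WT HT). On log2(FPKM + 1) with no filter it called 874 (genotype HT W2.5), 1958 (temperature WT W2.5), 224 (stage WT LT), 1765 (stage WT HT), 477 (stage mads1 LT), 226 (interaction W2.5) and 515 (interaction W3.5).

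Without WT_HT_W2.5 replicate 3 and mads1_HT_W3.5 replicate 3 the counts were 1187 (genotype LT W2.5), 3076 (genotype LT W3.5), 1215 (genotype HT W2.5), 2778 (genotype HT W3.5), 5226 (temperature WT W3.5), 6320 (temperature mads1 W2.5), 9397 (temperature mads1 W3.5), 845 (stage WT LT), 2607 (stage WT HT), 1641 (stage mads1 LT), 4855 (stage mads1 HT), 369 (interaction W2.5) and 2302 (interaction W3.5). Leaving out 1 library at a time gave ranges of 301 to 1047 (genotype LT W2.5), 291 to 2615 (genotype LT W3.5), 579 to 5750 (genotype HT W2.5), 442 to 4572 (genotype HT W3.5), 1493 to 6842 (temperature WT W2.5), 551 to 4836 (temperature WT W3.5), 735 to 5808 (temperature mads1 W2.5), 3798 to 10157 (temperature mads1 W3.5), 36 to 660 (stage WT LT), 850 to 7258 (stage WT HT), 165 to 1419 (stage mads1 LT), 818 to 5462 (stage mads1 HT), 80 to 1206 (interaction W2.5), 123 to 2636 (interaction W3.5). The highest came without WT_HT_W2.5 replicate 3, except for genotype HT W2.5, temperature WT W2.5, stage WT HT and interaction W2.5, where it came without WT_HT_W2.5 replicate 1.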

Other observations

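Genes present in mads1 and absent in WT outnumbered the reverse. Off in every WT library and on in every mads1 library of the same group were 31 genes at LT W2.5, 29 at LT W3.5, 27 at HT W2.5 and 25 at HT W3.5, while 2, 7, 1 and 0 genes showed the opposite. HORVU2Hr1G031640 stood at 310 ± 32.9 CPM in mads1 at LT W2.5 and 318 ± 17.6 at HT W2.5, but at 20.7 ± 34.5 at HT W3.5. The largest of these 3 HT W3.5 libraries read 60.5 CPM and the smallest 0.395.

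Private genes, at 5 CPM or more in one library and under 1 CPM in the other 23, numbered 20 in WT_HT_W2.5 replicate 3, 18 in mads1_HT_W3.5 replicate 3 and 0 in each other library.

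The tests of 2 hypotheses on sampling time were chosen after the results were seen. The lower MADS members in mads1 at LT W2.5 might come from spikes sampled earlier in development. Over 2141 genes called between stages in WT at HT, the genotype effect correlated with the stage effect at rho = -0.08. The lower MADS members in WT at HT W2.5 might likewise come from earlier spikes. Over 1419 genes called between stages in mads1 at LT, the temperature effect correlated at rho = -0.12. Both values have the sign that earlier sampling would give and are small, noise in the effects lowers such a correlation, and neither hypothesis can be decided by them. Both used the fit without WT_HT_W2.5 replicate 3.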
